A study of Homo sapiens with 12 samples.

How the data were processed

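The data are 12 one-colour Affymetrix whole-transcript arrays of the Hodgkin lymphoma lines L-1236 and U-HO1. Per the labels' protocols, L-1236 was grown in RPMI 1640 and U-HO1 in IMDM, cells were transduced with an shRNA against GATA-3 or a control shRNA, cultured for 3 days and sorted for GFP, and RNA of 25000 cells was amplified before labelling. The values are those of the deposited table, which the authors normalized and which hold a log scale taken here as log2 from their range of 3.86 to 13.99. R 2.8.1 with Bioconductor was used upstream, per the submitters' processing notes and design text. The background correction, normalization and summary method are not given in the sources used here, and a variance-stabilising step that shortens folds of dim probe sets cannot be ruled out, so log base and fold sizes rest on that reading. The columns are not quantile-identical: after sorting, arrays differ by up to 0.52, and the SD over probe sets runs from 1.62 to 1.72. The column medians are 7.09, 7.03 and 7.05 for L-1236 labelled control replicates 1, 2 and 3, 7.02, 7.00 and 6.96 for L-1236 labelled knockdown, 7.00, 7.06 and 7.01 for U-HO1 labelled control and 7.03, 7.03 and 7.03 for U-HO1 labelled knockdown. No array equals another.

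The table holds 32321 probe sets. Through the platform's annotation 19158 have 1 gene symbol, 1388 have several and 11775 are unnamed here, which gives 18404 genes, and 19128 of those with 1 symbol were found by Entrez identifier in a current gene table of the GRCh38.p14 assembly, used for names only, which changed 0 symbols. Only probe sets with 1 symbol were named. Where a gene has several, the one with the highest mean over the 12 arrays stands for it, and others are mentioned where they disagree. No genome build is named in the sources used here, so no coordinates are given.

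Groups follow the labels: 3 arrays each of L-1236 and U-HO1 labelled control and labelled knockdown. All 12 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 8 residual degrees of freedom, no filter on dim probe sets). Contrasts were knockdown against control in each line, the difference between these effects, their average, and control against control between the lines. P-values were adjusted by Benjamini and Hochberg over all probe sets. Counts are given by the criteria stated by the submitters, a false discovery rate of at most 25% with a fold of at least 1.5, and at an adjusted p under 0.05. Between the lines a fold of at least 2 was also asked. GATA3 was tested by exact permutation within each line. For 34 gene lists with 942 members, 860 of them measured, camera was run with a preset correlation of 0.01 and with an estimated one, and fry as a directional test. Lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined.

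Genes named are GATA3, IL5, IL13, STAT4, CCL17, CCL22, IL4 and TNFRSF8 in the comparisons within and between lines; for a knockdown comparison without passing probe sets, the 5 smallest p each way; for the difference and the average, the 3 smallest p each way; for the lines, the 10 largest differences each way at an adjusted p under 0.05; and up to 4 members with the smallest p of each list described. Genes without a proper symbol, pseudogenes and sex-linked controls were passed over. The fit was tested on simulated data of the same size, with 200 probe sets changed by known folds. These data took the measured control means and the spread of each probe set, with normal noise drawn independently for each value. Alternatives were a replicate block, quantile normalization, centring of array medians, leaving out dim probe sets, 1 probe set per gene, only the 6 arrays compared, a trended and robust prior, array quality weights (statmod 1.5.0), a test against the fold limit, and leaving out each array in turn. Alternatives added after seeing the data were the lines compared over both labels, every count without the arrays labelled knockdown replicate 1 and control replicate 3 of each line, and the mean difference of each list called in a knockdown comparison without each array in turn.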

Results

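Gene expression was measured on 12 arrays from L-1236 and U-HO1, established cell lines of Hodgkin lymphoma, a B-cell-derived tumour. Cells of each line were transduced with an shRNA against GATA-3, the transcription factor that directs T-helper 2 differentiation, or with a control shRNA lacking function. After 3 days of culture, 25000 GFP-positive cells were sorted per sample and their RNA was amplified and hybridised to a whole-transcript array. There were 4 groups of 3 arrays, with 6 arrays per line. Array medians lay between 6.96 and 7.09 on the log2 scale. Arrays of one line correlated across probe sets at 0.986 to 0.995, and arrays of different lines at 0.939 to 0.951. The submitters call the samples of a group independent without saying how, so the p-values measure the spread between these arrays, and the number of arrays limits their precision.

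GATA3 was read first on every array, as the target of the shRNA. In L-1236 the arrays labelled control read 10.29, 10.69 and 9.95 for replicates 1, 2 and 3, and those labelled knockdown read 10.80, 10.00 and 10.24. In U-HO1 the arrays labelled control read 11.24, 10.90 and 10.24, and those labelled knockdown read 11.07, 10.12 and 10.22. The mean GATA3 level in L-1236 was 10.34 ± 0.41 (SD, n = 3) on arrays labelled knockdown and 10.31 ± 0.37 on arrays labelled control, a log2 difference of 0.03 with a 95% interval from -0.64 to 0.71. In U-HO1 it was 10.47 ± 0.52 against 10.79 ± 0.51, a log2 difference of -0.32 with a 95% interval from -1.003 to 0.36. Exact two-sided permutation tests gave p = 0.9 in L-1236 and p = 0.5 in U-HO1, where the smallest p possible was 0.1, and p = 0.565 for both lines together. GATA3 therefore went against the label on some arrays: knockdown replicate 1 read above control replicates 1, 2 and 3 in L-1236 and above control replicates 2 and 3 in U-HO1, and control replicate 3 was the lowest of the 6 arrays in L-1236. Below, arrays are called by their labels only, and each direction between knockdown and control is that of the labels.

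**Figure D1:**
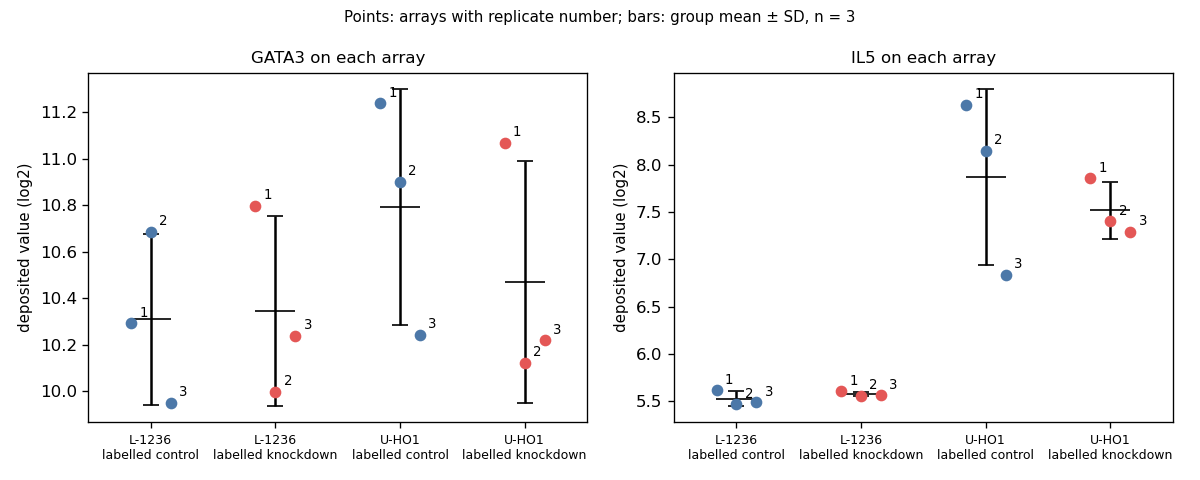
Deposited log2 values of GATA3 (left) and IL5 (right), vertical axes, on each array in the 4 labelled groups, horizontal axes. Points are arrays with their replicate number and bars are the group mean ± SD (n = 3); GATA3 in U-HO1 ran from 10.12 to 11.24, with arrays of both labels at either end.

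The first comparison asked which transcripts depend on GATA-3 in L-1236. GATA3 itself differed by 0.03, and the T-helper 2 cytokines IL5 and IL13 differed by 0.05 (SE 0.33) and -0.09 (SE 0.15) on the log2 scale between arrays labelled knockdown and control (n = 3 each). The chemokines CCL17 and CCL22, which attract T cells to Hodgkin tumours, differed by -0.06 (SE 0.11) and -0.32 (SE 0.28). STAT4 differed by 0.04 (SE 0.11), IL4 by 0.04 (SE 0.06), and TNFRSF8, which encodes the Hodgkin marker CD30, by 0.07 (SE 0.15). Each SE rests on the spread within all 4 groups, so the 0.33 of IL5 holds the spread in U-HO1 too. On the L-1236 arrays IL5 read 5.47 to 5.61 and IL4 5.66 to 5.80. These levels are not shown to lie above background, so a fall of either might not show. No probe set passed the submitters' criteria of a false discovery rate of at most 25% and a fold of at least 1.5, nor an adjusted p of 0.05, by limma (0 of 32321). At an unadjusted p under 0.05 there were 1542 probe sets against 1616.1 expected by chance, and the smallest adjusted p was 0.898. A fold of at least 1.5 without regard to p was reached by 61 probe sets, 26 positive and 35 negative. The smallest p among positive differences belonged to TMEM230, with a log2 difference of 0.30 (SE 0.08), MSC with 0.36 (SE 0.09), RNF185 with 0.36 (SE 0.09), AP2M1, a clathrin adaptor subunit, with 0.32 (SE 0.09), and NQO1, a quinone reductase, with 0.48 (SE 0.13). Among negative differences it belonged to MPRIP with -0.33 (SE 0.08), the microRNA gene MIR181A2 with -0.27 (SE 0.07), ANP32A-IT1 with -0.38 (SE 0.10), HECW1-IT1 with -0.47 (SE 0.13) and the small nucleolar RNA SNORA14A with -0.31 (SE 0.08). The adjusted p of these 10 was 0.925. Without the array labelled control replicate 3, 22 probe sets passed the submitters' criteria, and with array quality weights 1 did.

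Gene groups were then compared in L-1236. Of the 34 lists, camera with a preset correlation placed 8 above other genes and 1 below at an adjusted p under 0.05. The interferon-response list of 42 measured genes had a median log2 difference of 0.50, with 35 members positive and 7 negative (adjusted p = 6.19e-05 with the preset value, and adjusted p = 0.693 with an estimated correlation). The estimated correlation was 0.81 for this list, far above the preset 0.01, under which its p comes out too small. Its members with the smallest p were EIF2AK2, the double-stranded-RNA-activated kinase, with 0.48 (SE 0.23), SP110 with 0.44 (SE 0.23), SAMD9L with 0.83 (SE 0.43) and IFI44L with 0.83 (SE 0.44). The mean of the list was 7.88, 7.71 and 9.54 on the arrays labelled control replicates 1, 2 and 3, and 8.85, 9.38 and 8.27 on those labelled knockdown, so the groups overlapped. The difference of these means, 0.46, was 0.12 without control replicate 2 and 1.04 without control replicate 3. MHC class I genes had a median of 0.20, or 0.13 after quantile normalization (preset adjusted p = 0.00302), with 0.28 (SE 0.14) for the peptide trimming enzyme ERAP1 and 0.14 (SE 0.09) for TAPBP, which loads peptides. Their adjusted p = 0.687 with an estimated correlation, and their mean overlapped between the labels too, at 9.88, 10.03 and 10.49 on the arrays labelled control and 10.28, 10.42 and 10.26 on those labelled knockdown, with control replicate 3 the highest of the 6 for this list as for the interferon-response list. The difference of the MHC class I means, 0.18, was 0.059 without control replicate 1 and 0.36 without control replicate 3. The cytosolic ribosome (median 0.07, or 0.03 after quantile normalization, preset adjusted p = 0.000871) included RPS15 at 0.26 (SE 0.08) and RPS27 at 0.29 (SE 0.10), and had adjusted p = 0.693 with an estimated correlation. Oxidative phosphorylation (median 0.09, or 0.02 after quantile normalization, preset adjusted p = 0.000871) included ATP5PB at 0.17 (SE 0.07) and COX8A at 0.26 (SE 0.11), and had adjusted p = 0.687 with an estimated correlation. The means of these 2 lists overlapped as well, the ribosome at 11.24, 11.12 and 11.13 on arrays labelled control and 11.22, 11.17 and 11.35 on those labelled knockdown, and oxidative phosphorylation at 9.36, 9.40 and 9.34 and 9.32, 9.49 and 9.61. Without knockdown replicate 3 their differences were 0.033 instead of 0.086 and 0.035 instead of 0.10. The unfolded protein response, integrated stress response, heat shock and JAK-STAT lists were also placed above other genes as deposited, at preset adjusted p = 0.00365, 0.0131, 0.0156 and 0.0152, and each had adjusted p = 0.687 with an estimated correlation. Their medians were 0.11, 0.14, 0.09 and 0.06 as deposited and 0.02, 0.07, 0.04 and 0.05 after quantile normalization, and camera was not run on those values. The means overlapped between the labels for the integrated stress response and JAK-STAT. Without control replicate 1 their differences were 0.042 instead of 0.12 and 0.044 instead of 0.097. The unfolded protein response means did not overlap, at most 9.5414 on control and at least 9.5485 on knockdown arrays. Neither did those of heat shock, at 9.3875 and 9.3887. By chance 3 arrays part from 3 in 10% of cases. The list of GATA3 targets known from breast tissue was placed below, with a median of -0.04 (preset adjusted p = 0.0131), -0.0064 after quantile normalization, or 0.025 after centring of the arrays, which moved the median of all probe sets alike, from -0.0091 to 0.054, and left the place of the list among them as it was. It had adjusted p = 0.687 with an estimated correlation. Its means overlapped between the labels, at 7.30, 7.21 and 7.22 on arrays labelled control and 7.17, 7.22 and 7.15 on those labelled knockdown. No member of any list passed at an adjusted p under 0.05 over all genes, and 0 passed adjusted over the list alone. The T-helper 2 list (25 genes) had a median of 0.03 and camera adjusted p = 0.705.

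**Figure D2:**
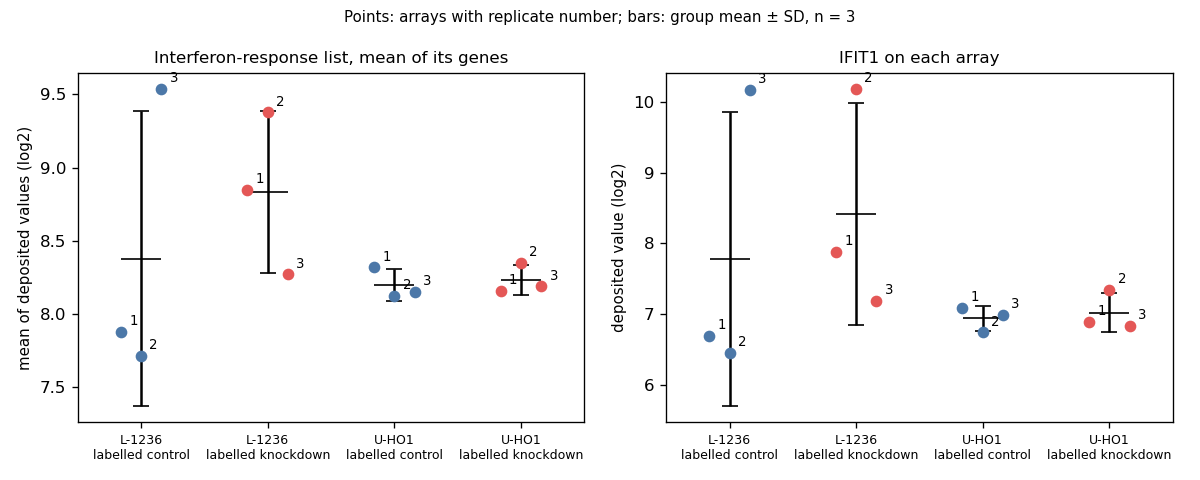
Mean log2 value of the 42 interferon-response genes (left) and log2 value of IFIT1 (right), vertical axes, on each array in the 4 labelled groups, horizontal axes. Points are arrays with their replicate number and bars are the group mean ± SD (n = 3); IFIT1, chosen after its values were seen, ran from 6.45 to 10.19 in L-1236, with arrays of both labels above 10.1.

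The same question was put to U-HO1. IL5 differed by -0.35 (SE 0.33) on the log2 scale between arrays labelled knockdown and control, with arrays labelled control at 8.63, 8.14 and 6.83 and arrays labelled knockdown at 7.86, 7.40 and 7.29. IL13 differed by -0.05 (SE 0.15), IL4 by 0.06 (SE 0.06), STAT4 by 0.05 (SE 0.11), CCL17 by -0.03 (SE 0.11), CCL22 by 0.21 (SE 0.28) and TNFRSF8 by -0.05 (SE 0.15). By limma 0 of 32321 probe sets passed the submitters' criteria and 0 had an adjusted p under 0.05. There were 339 at an unadjusted p under 0.05 against 1616.1 expected by chance, and 6 with a fold of at least 1.5, of which 5 were positive. With fewer small p-values than chance gives, the test may be conservative here, and the counts of 0 do not show that nothing changed. The smallest p among positive differences belonged to the zinc finger genes ZNF285 with 0.30 (SE 0.07), ZNF691 with 0.22 (SE 0.08) and ZKSCAN7 with 0.20 (SE 0.08), the antisense RNA LIF-AS2 with 0.22 (SE 0.08) and CST9 with 0.23 (SE 0.09). Among negative differences it belonged to the chemokine gene XCL2 with -0.31 (SE 0.09), LYZL2 with -0.29 (SE 0.10), SNORD115-8 with -0.20 (SE 0.07), MIR133B with -0.25 (SE 0.09) and SNORD8 with -0.23 (SE 0.09). All 10 had an adjusted p of 1.00. A pair of gene groups stood apart by camera with a preset correlation. Hypoxia and glycolysis genes had a median of 0.07, with 30 of 32 positive (preset adjusted p = 4.91e-05, and adjusted p = 0.971 with an estimated correlation), among them the glucose transporter SLC2A3 at 0.26 (SE 0.13) and PFKFB4 at 0.21 (SE 0.13). Core histones had a median of -0.09, with 34 of 39 negative (preset adjusted p = 0.000419, and adjusted p = 0.971 with an estimated correlation), among them H2AC6 at -0.20 (SE 0.15) and H3C11 at -0.25 (SE 0.21). The list means overlapped between the labels: hypoxia and glycolysis read 9.39, 9.24 and 9.44 on arrays labelled control replicates 1, 2 and 3 and 9.57, 9.37 and 9.36 on those labelled knockdown, and core histones read 8.52, 8.75 and 8.76 and 8.76, 8.38 and 8.64. Without knockdown replicate 1 the difference of the hypoxia and glycolysis means was 0.011 instead of 0.080, and without knockdown replicate 2 that of the core histone means was 0.022 instead of -0.086. By limma 0 members of either list passed at 0.05, over all genes or adjusted over the list alone. The T-helper 2 list had a median of 0.05 (adjusted p = 0.742) and the interferon-response list one of 0.04 (adjusted p = 0.874).

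The effects in the lines were set against each other. No probe set passed the submitters' criteria in both lines, and the log2 differences of L-1236 and U-HO1 correlated at -0.0023 across probe sets, which are not independent replicates. At an unadjusted p under 0.05 in both lines there were 45 probe sets, against 16.2 expected of independent lists. Both comparisons share 1 variance estimate per probe set, so the lists are not independent and the excess cannot be read as shared effects. Of the 45, 18 went the same way and more went opposite ways. For the difference between the lines, limma gave 0 probe sets at an adjusted p under 0.05, and 795 at an unadjusted p under 0.05, against 1616.1 expected by chance. The smallest p belonged to MIRLET7D at 0.41 (SE 0.11), TIMP2 at 0.36 (SE 0.10) and ZNF285 at 0.35 (SE 0.10), in the sense of U-HO1 minus L-1236, and to C1D at -0.65 (SE 0.18), KLRC2 at -0.37 (SE 0.12) and TMEM230 at -0.34 (SE 0.11). The difference of GATA3 between arrays labelled knockdown and control was -0.36 in the same sense, U-HO1 minus L-1236 (limma adjusted p = 0.9997). The average over both lines also had 0 probe sets at an adjusted p under 0.05 by limma and 733 at an unadjusted p under 0.05, again fewer than chance gives. Its smallest p belonged to RNF185 at 0.25 (SE 0.06), CYRIA at 0.22 (SE 0.06) and PERP at 0.22 (SE 0.06), and to SNORA14A at -0.24 (SE 0.06), MPRIP at -0.22 (SE 0.06) and SNORD8 at -0.24 (SE 0.06). For the average, camera placed 7 lists above other genes with the preset correlation, led by the interferon-response list (median 0.26, adjusted p = 0.000183) and hypoxia and glycolysis (median 0.06, adjusted p = 0.000183). The 7 had adjusted p = 0.841 with an estimated correlation, and after quantile normalization the medians of these lists were 0.23 and 0.05. The interferon-response average came mostly from L-1236, where the median was 0.50. With single arrays left out, the difference of its means in L-1236 ran from 0.12 to 1.04. That of hypoxia and glycolysis in U-HO1 ran from 0.011 to 0.12.

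In simulated data of the same size, the fit recovered 40% of probe sets changed 1.5-fold in L-1236 and 96% of those changed 2-fold by the submitters' criteria, and 46% and 98% in U-HO1. Chance calls numbered 14 and 15 in those simulations. Their noise was independent between probe sets and arrays and was drawn 1 time per line. Structure among the real arrays did not enter, so these shares and counts need not hold for the measured data. Without the arrays labelled knockdown replicate 1 and control replicate 3 of each line, a choice made after seeing the data, 0 probe sets passed by limma in either line or differed between the lines, with 2795 in L-1236, 1005 in U-HO1 and 1201 for the difference at an unadjusted p under 0.05. In the average over both lines 1 then had an adjusted p under 0.05 and 38 passed the submitters' criteria.

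The arrays labelled control also showed how U-HO1 and L-1236 differed, which includes the difference between their culture media, IMDM and RPMI 1640. By limma 8343 probe sets had an adjusted p under 0.05, 4296 higher and 4047 lower in U-HO1. Of these 1614 differed at least 2-fold, 868 higher and 746 lower, which correspond to 1286 named genes. LRRN3, a leucine-rich repeat protein of neurons, was 77.4-fold higher in U-HO1, at 12.09 ± 0.11 against 5.82 ± 0.07 (SD, n = 3, adjusted p = 7.13e-13). FAM9C was 60.0-fold higher, the lymphoid adaptor SAMSN1 34.1-fold, and the small nucleolar RNAs SNORD116-14 and SNORD116-15 of the imprinted Prader-Willi locus 37.2-fold and 34.0-fold. DIAPH2-AS1 (30.1-fold), the glutamine transporter SLC38A1 (28.4-fold), the thymocyte selection gene THEMIS (27.5-fold), the phosphoinositide kinase PIK3CG (26.5-fold) and the potassium channel KCNH7 (25.3-fold) were also higher. The heparan sulfatase SULF1 was 44.8-fold lower in U-HO1, at 6.13 ± 0.24 against 11.61 ± 0.15 (adjusted p = 4.16e-11). SLC16A4 was 36.0-fold lower, the leukotriene receptor CYSLTR2 31.3-fold, AOAH, which inactivates bacterial lipopolysaccharide, 30.9-fold, and the IgE receptor chain FCER1A 30.8-fold. CEP15 (27.5-fold), the lipoxygenase ALOX15 (26.6-fold), the chemokine CCL2 (22.7-fold), the interleukin-1 receptor IL1R1 (21.5-fold) and MLLT11 (19.3-fold) were lower too. The largest adjusted p among these 20 was 5.7e-08. Their means in the line with the lower level lay between 4.90, for SNORD116-14, and 7.16, for SLC38A1, and background is not given on these arrays. These folds and those below are therefore ratios of measured values, and their size and order depend on the background where the lower level is dim.

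GATA3 was 10.79 ± 0.51 in U-HO1 and 10.31 ± 0.37 in L-1236 on arrays labelled control, a difference that did not pass the test (log2 0.48, adjusted p = 0.323). IL5 was 5.09-fold higher in U-HO1, at 7.87 ± 0.93 against 5.52 ± 0.08 (n = 3, adjusted p = 0.00023), a level in L-1236 not shown to lie above background, IL13 1.74-fold higher (adjusted p = 0.00154), STAT4 8.99-fold higher (adjusted p = 2.13e-09) and CCL17 1.69-fold higher (adjusted p = 0.000342). CCL22 was 4.14-fold lower (adjusted p = 0.000176) and TNFRSF8 1.60-fold higher (adjusted p = 0.00544), while IL4 was 5.71 ± 0.04 against 5.71 ± 0.05 (adjusted p = 0.951). Of 25 T-helper 2 genes, 8 were higher and 5 lower at an adjusted p under 0.05 (13 adjusted over the list alone). CCR4, the receptor of CCL17 and CCL22, was 5.74-fold higher and the TSLP receptor CRLF2 11.9-fold higher, while IL4R was 2.25-fold lower and the IL-33 receptor IL1RL1 2.82-fold lower. Of 19 T-helper 1 genes, 3 were higher and 5 lower (8 adjusted over the list alone), with LTA 5.62-fold lower by its brightest probe set, -2.14 on the log2 scale by another, and EOMES lower at a log2 difference of -1.48 (SE 0.13). Among 36 cytokines and chemokines of Hodgkin cells, 6 were higher and 7 lower (13 adjusted over the list alone). CCL1 was 17.8-fold higher and IL6 3.40-fold lower.

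Signalling and lineage genes went both ways between the lines. Of 37 NF-kB genes, 11 were higher in U-HO1 and 12 lower (29 adjusted over the list alone), with TRAF1 7.62-fold higher and CD40 3.88-fold lower. Of 30 JAK-STAT genes, 8 were higher and 9 lower (22 adjusted over the list alone), with IL2RB 4.49-fold higher, and IL10RA 3.99-fold and PIM2 2.57-fold lower. Notch genes included MFNG, which glycosylates Notch receptors, 3.61-fold lower and the ligands DLL1 and JAG2 2.14-fold and 2.37-fold lower, among 5 higher and 6 lower of 26 (12 adjusted over the list alone). Of 30 genes listed as Hodgkin surface genes, 9 were higher and 12 lower (22 adjusted over the list alone). The receptor tyrosine kinase MET was 6.38-fold, CD83 3.05-fold and FSCN1, whose product is not a surface protein, 2.62-fold higher. B-cell genes included the B-lineage regulator PAX5 3.93-fold and CD22 5.83-fold lower, the low-affinity IgE receptor FCER2 lower at a log2 difference of -2.32 (SE 0.18), and IKZF3 2.58-fold higher, among 7 higher and 7 lower of 32 (17 adjusted over the list alone). Of 13 plasma cell genes, 3 were higher and 2 lower (6 adjusted over the list alone), with the differentiation regulator PRDM1 8.92-fold higher. Of 21 genes of factors that work with GATA factors, 4 were higher and 4 lower (8 adjusted over the list alone). RUNX1 was 4.21-fold and RUNX2 3.15-fold higher, and FLI1 2.34-fold and ETS1 1.94-fold lower. Of 26 T-cell genes, 1, TOX, was higher (10.6-fold) and 5 were lower (6 adjusted over the list alone), among them CD4 (3.25-fold). Of 25 myeloid genes, 2 were higher and 3 lower (4 adjusted over the list alone), with CD68 4.68-fold higher and FCGR2A 10.8-fold lower, with a mean of 5.37 in U-HO1. Of 17 NK-cell genes 0 passed at an adjusted p under 0.05 by limma, and 0 adjusted over the list alone.

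Genes of the cell cycle, of mitochondria and of antigen presentation were compared in the same way. Of 38 genes of the G2 and M phases, 25 were higher in U-HO1 and 0 lower at an adjusted p under 0.05 (32 adjusted over the list alone), with a median log2 difference of 0.84. The mitotic kinase AURKB was 2.85-fold higher, at 11.13 ± 0.09 against 9.62 ± 0.39, CDK1 2.73-fold and PTTG1 2.11-fold higher, and BIRC5 2.06-fold higher by its brightest probe set and 0.37 on the log2 scale by another. Camera gave the list adjusted p = 5.51e-09 with the preset correlation, and adjusted p = 0.971 with an estimated correlation. The estimate was 0.85 for this list, far above the preset 0.01, under which p comes out too small. It was 0.77 for G1 to S, 0.52 for MHC class I and 0.29 for oxidative phosphorylation. Of 33 genes of the G1 to S transition, 11 were higher and 2 lower (15 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.971 with an estimated correlation), with TK1 2.51-fold higher and the replication helicase subunit MCM4 higher at a log2 difference of 1.58 (SE 0.25). Of 36 oxidative phosphorylation genes, 17 were higher and 0 lower (20 adjusted over the list alone, camera adjusted p = 0.000779, and adjusted p = 0.971 with an estimated correlation), among them CYC1 (1.84-fold) and COX8A (1.83-fold). MHC class I genes included TAP2 2.54-fold and TAP1 2.34-fold lower, which carry peptides into the endoplasmic reticulum, and ERAP2 2.79-fold lower. Other probe sets of TAP2 gave log2 differences of -1.23 and -2.36. Of 11, 0 were higher and 7 lower (7 adjusted over the list alone, camera adjusted p = 0.00155, and adjusted p = 0.971 with an estimated correlation). On arrays labelled control the MHC class I mean ran from 9.88 to 10.49 in L-1236 and from 9.34 to 9.52 in U-HO1. These ranges did not overlap, but the size of the difference varies with the L-1236 array. Fry, which asks only whether a list's own genes move one way, gave adjusted p = 0.0203 for G2 and M, 0.187 for G1 to S, 0.00972 for oxidative phosphorylation and 0.00666 for MHC class I. By fry 9 lists passed between the lines: besides G2 and M, oxidative phosphorylation and MHC class I, these were MHC class II, plasma cell and p53 target genes upward in U-HO1 (adjusted p = 0.00287 each), T-helper 2 and anti-apoptotic genes upward and Notch genes downward (adjusted p = 0.00666 each), lists that camera with the preset correlation did not call and whose passing members went both ways. Of 14 MHC class II genes, 8 were higher and 3 lower (11 adjusted over the list alone, camera adjusted p = 0.0609). The class II transactivator CIITA was 1.76-fold higher and HLA-DPB1 3.09-fold higher by its brightest probe set, with log2 differences of 1.27 and 0.30 by the others. Of 30 integrated stress response genes 4 were higher and 3 lower (7 adjusted over the list alone), and of 32 hypoxia and glycolysis genes 7 and 5 (15 adjusted over the list alone). The serine synthesis enzyme PHGDH was 7.94-fold higher and PSAT1, of the same pathway, 2.50-fold lower, while the glycolytic enzymes ALDOC and PFKM were 3.95-fold and 2.58-fold lower. Of 12 anti-apoptotic genes 5 were higher and 5 lower (10 adjusted over the list alone). Of 26 pro-apoptotic genes 7 were higher and 3 lower (10 adjusted over the list alone), with TNFSF10, which encodes TRAIL, 7.60-fold and its receptor TNFRSF10A 2.63-fold higher, and BCL2L11, which encodes BIM, 4.75-fold lower. Of 28 p53 targets 9 were higher and 2 lower (11 adjusted over the list alone), with DDB2 2.86-fold higher and CDKN1A, which encodes p21, 2.16-fold lower. The interferon-response list varied among the L-1236 arrays labelled control from 7.71 to 9.54, and 2 of its 42 members were higher and 2 lower (4 adjusted over the list alone, camera adjusted p = 0.822).

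**Figure D3:**
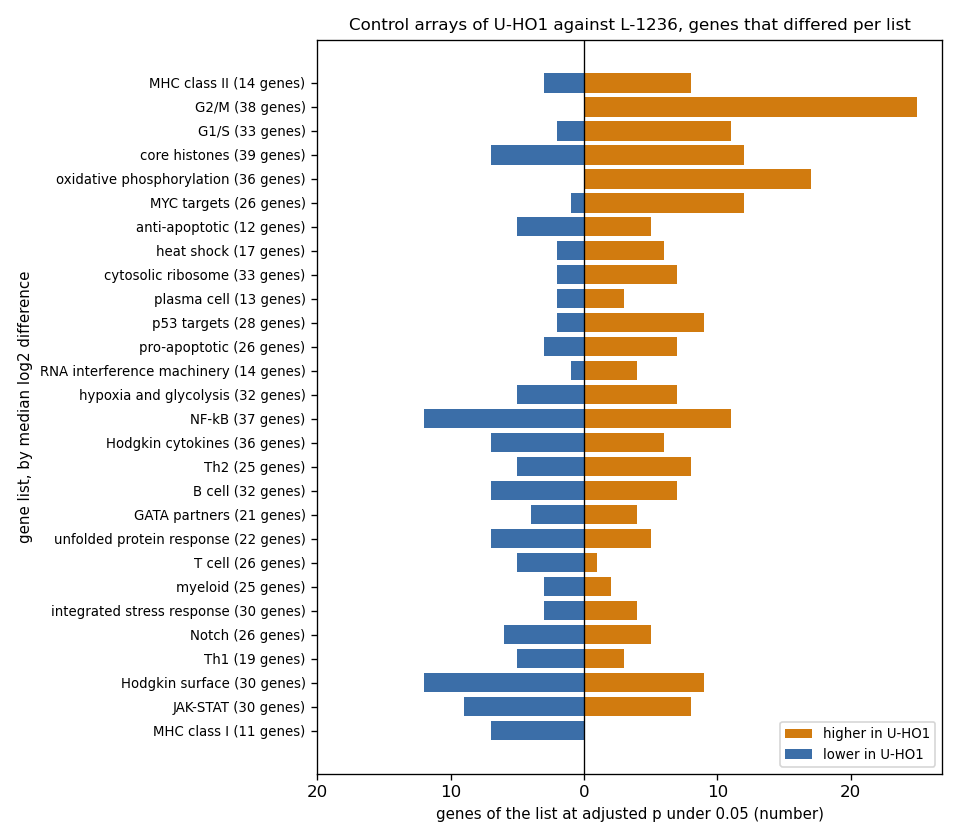
Number of genes per list, horizontal axis, that were higher (to the right) or lower (to the left) in U-HO1 than in L-1236 on arrays labelled control (limma adjusted p under 0.05, n = 3 each), for the lists with at least 5 such genes, ordered on the vertical axis by their median log2 difference. Of the 38 G2 and M phase genes 25 were higher and 0 lower, and of the 11 MHC class I genes 7 were lower.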

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

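The tests of the interferon pattern were chosen after the result was seen. By camera with a preset correlation, 9 of the 34 lists differed between the lines in their knockdown effect, U-HO1 minus L-1236, each direction being that of the labels. The cytosolic ribosome was lower in that sense (adjusted p = 0.000467), as were core histones (adjusted p = 0.00187), the interferon response (adjusted p = 0.00260), oxidative phosphorylation (adjusted p = 0.00487), MHC class I and the integrated stress response (adjusted p = 0.0113 for both), the unfolded protein response (adjusted p = 0.0331) and MHC class II (adjusted p = 0.0351). The list of breast GATA3 targets was higher (adjusted p = 0.0108) with a median of 0.06, or -0.0043 after centring of the arrays, which moved the median of all probe sets alike, from 0.0031 to -0.065, and left the place of the list among them as it was. After quantile normalization the medians of oxidative phosphorylation, the ribosome, the integrated stress response and the unfolded protein response were -0.02, -0.04, -0.08 and -0.03, against -0.10, -0.09, -0.16 and -0.06 as deposited. With an estimated correlation none of the 9 passed, with adjusted p = 0.794 for the interferon response and adjusted p = 0.743 for the other 8, and fry gave 0 of 34 lists, with adjusted p from 0.930. No member of these lists had an adjusted p under 0.05 by limma.

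Interferon-response genes differed between L-1236 arrays of one label. Of the 42 measured members, 34 ranged over more than 1 log2 unit across the 6 L-1236 arrays and 0 did across the 6 U-HO1 arrays; IFIT2 ran over 4.12 and MX1 over 2.92 in L-1236, against 0.50 and 0.82 in U-HO1. Scaling differences between arrays are argued against, since the range of the list mean in L-1236 was 1.82 as deposited and 1.88 after quantile normalization. Arrays labelled control alone spanned 1.82, while the labelled groups differed by 0.46. A knockdown as labelled cannot make arrays labelled control differ, so this restates the pattern and is no separate test. Whether the knockdown adds to the spread stays open. The exact two-sided permutation test gave p = 0.6, but its smallest p possible was 0.1, so it could not decide the question. A response to the transduction and a difference between cultures were not tested, and labels out of order, tested only through GATA3 and the fold changes of all probe sets, stay open too.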

How the results depend on the processing

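The comparison of the lines over both labels, the counts without knockdown replicate 1 and control replicate 3 of each line, and the list means with arrays left out, were chosen after seeing the data. Counts of 0 in both lines, in their difference, average and overlap were 0 in the other settings tried, apart from those that follow. For L-1236 by the submitters' criteria, array quality weights gave 1 probe set and leaving out single arrays gave 0 to 22, the 22 without the array labelled control replicate 3. Without those arrays, the average gave 1 at an adjusted p of 0.05 and 38 by the submitters' criteria, with fewer arrays. The GATA3 difference in L-1236 was -0.071 after quantile normalization and -0.037 with array weights, and -0.19 to 0.22 with single arrays left out (lowest without knockdown replicate 1, and -0.14 without control replicate 3); in U-HO1 it was -0.62 to -0.10, and -0.57 with array weights. The cause was not tested.

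With the replicate block, counts stayed 0 in the knockdown comparisons and were 8290 and 1610 between the lines. The numbers gave no clear pairing of the arrays: deviations of same-numbered arrays correlated with r of 0.17, -0.40 and -0.22 in L-1236 and -0.17, 0.06 and 0.32 in U-HO1. Knockdown replicate 1 of L-1236 and knockdown replicate 3 of U-HO1 correlated best with their own number, and the others did not. Other structure of the arrays enters these r, so a pairing is not excluded. Between the lines, 7049 to 8128 probe sets had an adjusted p under 0.05 with single control arrays left out, and 1586 to 1783 differed at least 2-fold. Over both labels there were 1580 of the latter, 1460 of them shared with the comparison of arrays labelled control. Centring arrays gave a median shift of 0.035.

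Named genes between the lines kept direction and side of the threshold in 2254 of 2314 recomputed values, with 33 losing the threshold, 23 passing it and 4 turning. IL4 turned, to 0.025 after centring and -0.038 to 0.012 with arrays left out. Genes under the threshold in a knockdown comparison changed sign as follows, the cause not tested. In L-1236, TNFRSF8 was -0.026 after quantile normalization and CCL17 0.0045 after centring. With arrays left out, TNFRSF8 ran from -0.054 to 0.21, CCL22 from -0.57 to 0.017 and STAT4 from -0.042 to 0.12. In U-HO1, array weights gave TNFRSF8 0.045 and CCL17 0.076. With arrays left out, TNFRSF8 ran from -0.14 to 0.068, CCL17 from -0.10 to 0.11, STAT4 from -0.050 to 0.10, IL13 from -0.21 to 0.078 and IL5 from -0.87 to 0.027. Gene list calls by camera were lost with an estimated correlation in the 31 cases, and fry kept 3, G2 and M, MHC class I and oxidative phosphorylation between the lines. With single arrays left out, the knockdown difference of a list mean in L-1236 was 0.12 to 1.04 for the interferon response, 0.059 to 0.36 for MHC class I, 0.033 to 0.13 for the ribosome, 0.035 to 0.18 for oxidative phosphorylation, 0.042 to 0.20 for the integrated stress response, 0.044 to 0.15 for JAK-STAT, 0.061 to 0.12 for heat shock, 0.077 to 0.12 for the unfolded protein response and -0.080 to -0.032 for breast GATA3 targets. In U-HO1 it was -0.17 to 0.022 for core histones, positive only without knockdown replicate 2, and 0.011 to 0.12 for hypoxia and glycolysis. Signal over background is not given on these arrays.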

Other observations

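The tests of a batch, of the GATA3 probe set's level and of levels that follow GATA3 were chosen after the result was seen; the counts over other splits and the test of the labels were planned. The mean of the G2 and M phase list was 8.65, 9.42 and 8.88 on L-1236 arrays labelled control replicates 1, 2 and 3 and 8.93, 8.75 and 9.44 on those labelled knockdown, a range of 0.792, against 0.315 over the U-HO1 arrays. MKI67, chosen after its values were seen, ran from 9.56 to 10.77 in L-1236, both on arrays labelled control. Cholesterol synthesis genes had the widest list range among the U-HO1 arrays, 0.582, with means of 8.94, 9.16 and 9.53 on arrays labelled control and 9.21, 8.99 and 9.48 on those labelled knockdown. In L-1236 that list ranged over 0.385.

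In both lines GATA3 was high on the array labelled knockdown replicate 1, and on the array labelled control replicate 3 it was the lowest in L-1236 and, in U-HO1, 10.24 against 10.12 and 10.22 on knockdown replicates 2 and 3. A probe set too dim is argued against, as the mean GATA3 value of 10.48 lies at the 94.9th percentile of probe sets. That mean also lies below the highest mean of 13.87, but other probe sets do not show the level at which this one saturates. Labels out of order could account for it, as a hypothesis; the test set beforehand, that 1 split shared by both lines gives the highest absolute correlation of their fold changes without GATA3, was not met over all probe sets, where different splits gave 0.415, the labelled split gave -0.0023, and the split of control 1, knockdown 1 and control 2 against the rest, which in both lines parts the 3 arrays with the higher GATA3 from the 3 with the lower, gave 0.348, ranking 4 among the 100 pairs. By the reading set beforehand, different splits in the 2 lines counted against the hypothesis. After the result was seen, that reading was judged too strict. The design does not tie an error in one line to the other, and other splits gave more calls than the labelled one. In all 4 sets of probe sets tried, the split of control 1, knockdown 1 and control 2 ranked 1 among the 10 pairs with the same split in both lines. These sets share values and are not separate tests. Only 2 sets met the test, both limited after seeing the data to 1 brighter probe set per gene (0.479, and 0.470 after quantile normalization). So the hypothesis failed the test set beforehand and stays open only under the later reading. A batch between the arrays deposited first and last in each line, for which 0.348 is also the value, cannot be told apart from it because no label gives a batch. The 95% intervals of the GATA3 difference between the labels, -0.64 to 0.71 in L-1236 and -1.003 to 0.36 in U-HO1, held both no change and a fall. By themselves these values therefore do not require labels out of order or a batch.

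Other splits of the arrays were counted for each comparison. In L-1236 the labelled split gave 0 probe sets by the submitters' criteria and 0 at an adjusted p under 0.05, and the highest of the other splits gave 106 and 66; all 10 splits gave as many as the labelled one. In U-HO1 the labelled split gave 0 and 0 and the highest of the others 160 and 1, with all 10 giving as many. Against a count of 0 all 10 splits give as many by construction in either line, so these shares neither exclude chance nor speak for it. The split of control 1, knockdown 1 and control 2 against the rest gave 4 by the submitters' criteria in L-1236 and 11 in U-HO1, or 8 and 16 after quantile normalization. Between the lines, fitted on the 6 arrays labelled control alone, the real split gave 7003, the highest other 0, and 1 split of 10 gave as many. Each other split mixes the lines on both sides, so the line difference enters the spread within a side and lowers the calls. The 0 is therefore no measure of what chance gives. With 10 splits the share cannot fall under 0.05. For the difference between the lines and for the average, the labels gave 0 and the highest of the 100 drawn splits 11 in each case; against a count of 0 all 100 splits give as many by construction, so this count neither excludes chance nor speaks for it. The splits with 106 and 160 calls, many more than the labelled ones, point to a structure of the arrays, with the limits that each is the highest of 9 others, that the count such a highest split reaches without structure was not computed, and that the split with 160 had 1 at an adjusted p under 0.05. The split with 106, of control 1, control 2 and knockdown 3 against the rest of L-1236, parts the 3 arrays with the lower interferon-response mean from the 3 with the higher, as noticed after seeing the data.

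Of 7 genes set against GATA3 over the 6 L-1236 arrays, as levels that may follow GATA3 whatever the label, STAT4 had the largest absolute Pearson's r, -0.84 (exact permutation p = 0.0625, adjusted p = 0.369), with Spearman's rho of -0.89 (exact permutation p = 0.033, adjusted p = 0.204). IL4 followed with r = 0.74 (exact permutation p = 0.106, adjusted p = 0.369) and rho = 0.83 (exact permutation p = 0.058, adjusted p = 0.204). Without the 2 arrays farthest from the median GATA3, r was -0.96 for STAT4, but CCL17 also had r = -0.996, IL4 r = 0.89, IL5 r = 0.84 and CCL22 r = 0.83, so those 4 arrays do not single out STAT4. No gene passed the correction, the other 5 having an exact permutation p for Pearson's r from 0.399, so whether levels follow GATA3 stays open; labels out of order would not change these values. On the L-1236 arrays IL5 read 5.47 to 5.61 and IL4 5.66 to 5.80, not shown to lie above background. In U-HO1 GATA3 lay from 10.12 to 10.24 on 3 arrays and from 10.90 to 11.24 on the other 3, so no correlation was computed there. IL5 read 8.63, 8.14 and 6.83 for labelled control replicates 1, 2 and 3 and 7.86, 7.40 and 7.29 for labelled knockdown. STAT4 read 9.72, 9.59 and 9.80 and 9.95, 9.65 and 9.66. IL5 was higher on each of the 3 arrays with the higher GATA3 than on the other 3, as noticed after seeing the data. CCL17 and TNFRSF8 were lower on each of them, and IL13, STAT4, CCL22 and IL4 overlapped. For 1 gene such a parting comes by chance in 10% of cases.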
